A study of Mus musculus with 27 samples.

How the data were processed

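The authors deposited FPKM values for every gene, made by Cufflinks, in a separate table for each experiment. Their notes list bcl2fastq 2.20, cutadapt 1.18, STAR 2.5.2, Cufflinks 2.1.1, HTSeq 0.11.2, DESeq2 (version not given) and the GRCm39 build, without saying what each tool did or in which order. The tables hold 54920 and 55247 genes, and 45 repeated gene entries were dropped from each. Values that Cufflinks marked as failed are listed as 0: 43 values in 17 genes of experiment 1, among them *Rpl22* in 9 libraries, *Peg10* in 7, *Sptan1* in 5 and *Epha4* in 4. They were kept at 0. Read counts could not be recovered from the FPKM values. At the best step, 27.8% to 39.6% of the low values of a library lay within 0.1 of a whole multiple, against 20% by chance at a fixed step. The best of many steps was taken, so the share by chance is higher than that. As given in the tables, 98.9% of gene spans equal those of GRCm38 when starts are read as 0-based, and 94.6% of gene identifiers are in the GRCm38 annotation. Only 2.84% of the matched genes start at the same position as in GRCm38, so equal spans do not mean GRCm38 positions. An annotation of GRCm39 was not used here.

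The analysis was done in R 4.3.3 with limma 3.58.1. Values were transformed to log2(FPKM + 1), and genes with a mean FPKM of at least 1 over the libraries of an experiment were tested, 12780 in experiment 1 and 12830 in experiment 2. The pseudocount of 1 makes fold changes of genes near 0 smaller than their ratio of FPKM. A linear model with a term for each group was fitted in each experiment with empirical Bayes moderation and a mean-variance trend. There were 4 contrasts in experiment 1 and 6 in experiment 2, p-values were adjusted by Benjamini-Hochberg within each contrast, and 0.05 was the threshold. Intervals are at 95%. The exact test of 3 libraries against 3 cannot give a p under 0.1, so the calls rest on the variance shared across genes. Libraries of 3 against 3 do not overlap for 10% of genes by chance. Replicates of a group correlated at 0.968 to 0.984.

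Gene lists were written from general knowledge: 26 of pathways, 2 of RNA quality (ribosomal proteins, and heat shock with the unfolded protein response) and 6 of markers of other cells. They were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, where at least 5 members were measured. Camera with the correlation estimated for each list is given where it ends a call. That setting is stricter even where the estimate is under 0.01. For S3QEL with against without IL-1α in experiment 1, STAT3 targets had an estimate of 0.00359. Their camera adjusted p went from 0.000351 to 0.0889. A lost call therefore does not by itself show that the genes of a list are correlated. "Over the list alone" means that p-values were adjusted within the list. Another 3 lists were chosen after results were seen and appear only among the closing observations. Their p-values were adjusted over those 3 lists alone. The IL-1α sets hold genes called and moved at least 2-fold by IL-1α in the other experiment, so that a set never shares libraries with the contrast it is tested in.

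The design, the 34 lists, the settings, their alternatives and the rule for named genes were fixed before the data were examined. The rule names, for each contrast, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose higher mean is at least 5 FPKM, leaving out genes with placeholder symbols. Where nothing is called, it names the 3 genes with the smallest p. It adds up to 4 members with the smallest p of each list called, and 19 genes in the IL-1α contrasts and the contrasts of a compound during IL-1α: *Lcn2*, *C3*, *Cxcl10*, *Cxcl1*, *Ccl2*, *Il6*, *Socs3*, *Stat3*, *Gfap*, *Vim*, *Serpina3n*, *Nfkbia*, *Icam1*, *Vcam1*, *Ptgs2*, *Nqo1*, *Hmox1*, *Aqp4* and *Slc1a2*. Not every gene the rule names is printed.

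Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, a fit on only the groups of the contrast, robust moderation, the replicate number as a block, each replicate left out in turn, and a fold of at least 1.5. A pair of alternatives was added after the data were seen: failed values as missing in experiment 1, and protein-coding genes alone. The pipeline was tested on simulated tables with known changes. It called 82.1% to 93.8% of genes changed 1.5-fold, 92.3% to 100% of those changed 2-fold and 95.4% to 100% of those changed 4-fold, and 1.93% to 7.14% of its calls were false. The simulated noise was normal and independent between genes, without extreme values, so these rates may not hold for the real libraries. For the comparison of S1QEL with S3QEL, which share IL-1α libraries, 100 draws of simulated control noise gave the similarity that the shared control produces.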

Results

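Primary mouse astrocytes were profiled by bulk RNA sequencing of poly(A) RNA after 6 h of treatment, in 2 experiments that were tabulated separately. Experiment 1 holds 12 libraries: vehicle (DMSO), S3QEL, IL-1α, and IL-1α plus S3QEL. Experiment 2 holds 15: vehicle, S1QEL, IL-1α, IL-1α plus S3QEL, and IL-1α plus S1QEL. Each of the 9 groups has 3 libraries. Interleukin-1α (IL-1α) is an inflammatory cytokine that makes astrocytes reactive, and the S1QEL and S3QEL compounds suppress electron leak to oxygen, and so reactive oxygen species, at respiratory complexes I and III. The tables give FPKM without read counts, so the depth of the libraries is unknown. FPKM sums ran from 405869 to 420985 in experiment 1 and from 441400 to 604149 in experiment 2. Positions below are in GRCm39 per the submitters' notes, and a gene is said to have risen or fallen where its adjusted p in limma is under 0.05.

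IL-1α (3 ng/mL) against vehicle shows the inflammatory response itself, and chemokine genes rose the most. In experiment 1, *Cxcl1* (ENSMUSG00000029380, chromosome 5, 91039100 to 91040974, protein coding), which encodes a neutrophil-attracting chemokine, rose from 0.113 ± 0.145 to 956 ± 50.9 FPKM (mean ± SD, n = 3 per group; log2 fold change 9.76, SE 0.104, limma adjusted p = 8.75e-14). The monocyte chemokine gene *Ccl2* (ENSMUSG00000035385, chromosome 11, 81926397 to 81928279) rose from 3.82 ± 0.825 to 1289 ± 92.9 FPKM (log2 fold change 8.08, SE 0.123, adjusted p = 1.35e-12). *Lcn2* (ENSMUSG00000026822, chromosome 2, 32274645 to 32278264), which encodes the iron-binding secreted protein lipocalin 2, rose from 9.77 ± 1.26 to 1547 ± 20 FPKM (7.17, SE 0.108, adjusted p = 1.35e-12). The metalloreductase gene *Steap4* (ENSMUSG00000012428, chromosome 5, 8010457 to 8032213) rose from 1.54 ± 0.298 to 240 ± 14.9 FPKM (6.57, SE 0.118, adjusted p = 4.19e-12). Other large rises were in *Ccl7* (7.44), *Cxcl10* (7.10), *Cxcl2* (6.43), *Ccl5* (6.34), *Ptx3* (5.29) and *Gbp2* (5.19). *Ccl20* and *Nos2* were listed at 0 in all 3 vehicle libraries and reached 32.1 ± 0.285 and 17.8 ± 1.4 FPKM with IL-1α. The steepest fall was in *Dio2* (ENSMUSG00000007682, chromosome 12, 90691326 to 90705212), which encodes the deiodinase that activates thyroid hormone, from 57.3 ± 5.9 to 6.96 ± 1.19 FPKM (−2.88, SE 0.124, adjusted p = 6.56e-09). *Nr4a3* (−2.59), *Ptgfr* (−2.02), *Tmem100* (−2.00), *Ppp1r3c* (−1.99), *Rln3* (−1.97), *Ap1s3* (−1.86), *Sstr2* (−1.85), *Nr4a1* (−1.79) and *Elobl* (−1.65) also fell.

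Genes of NF-κB feedback rose almost without exception. *Nfkbia*, which encodes the inhibitor that retains NF-κB in the cytoplasm, rose from 12.2 ± 0.842 to 193 ± 3.61 FPKM (3.88, SE 0.0513, adjusted p = 5.07e-13). *Nfkbiz* (3.52), the adhesion receptor gene *Icam1* (3.21), *Vcam1* (2.66), *Il6* (4.07), *Ptgs2* (2.48), the complement gene *C3* (2.93), *Socs3* (0.84), *Stat3* (0.50), *Serpina3n* (0.34, adjusted p = 0.0282), *Hmox1* (0.37) and the water channel gene *Aqp4* (0.87) rose as well. The intermediate filament genes *Gfap* (−0.30, adjusted p = 0.00117) and *Vim* (−0.36, adjusted p = 2.87e-06) fell. *Slc1a2* (0.01, adjusted p = 0.959) and *Nqo1* (0.01, adjusted p = 0.981) were not called. In all, 2111 genes rose and 2558 fell of 12780 tested, 1122 of them by at least 1.5-fold. The values of the IL-1α and vehicle groups did not overlap for 49.8% of genes, against 10% by chance. The first principal component held 53.4% of the variance and separated every library with IL-1α from every library without it. Nothing in the labels says that replicates are separate cultures, so each p-value measures only the spread between samples.

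Gene lists fixed before the data were examined were tested with camera, a competitive test against all other genes. In experiment 1, 24 of 25 NF-κB feedback and target genes rose and 1 fell (median log2 fold change 2.1, camera adjusted p = 4.62e-24). Of 17 chemokine genes, 15 rose and 1 fell (median 3.64, adjusted p = 7.32e-16). Among 14 cytokine and colony-stimulating factor genes 10 rose, 11 when adjusted over the list alone (median 1.75, adjusted p = 5.75e-09), led by *Csf3* (4.39), *Csf2* (3.95), *Lif* (3.04) and *Csf1* (1.62). STAT3 targets and gp130 signalling genes gave 18 rises and 1 fall of 24, 19 and 1 over the list alone (median 0.66, adjusted p = 3.18e-11). All 15 measured MHC class I and antigen processing genes rose (median 1.17, adjusted p = 3.4e-15), among them *H2-Q4* (2.61), *H2-K1* (2.04) and *Tapbp* (1.23). Pan-reactive astrocyte genes rose in 9 and fell in 2 of 12 (median 0.72, adjusted p = 1.45e-06). The A2 list had 6 rises and 1 fall of 11, 8 and 2 over the list alone (median 0.38, adjusted p = 0.000236). These 7 lists kept their call when the correlation between genes was estimated from the data, with adjusted p from 0.00258 (STAT3) to 0.0372 (A2).

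The other 11 called lists lost their call with an estimated correlation. Interferon-stimulated genes rose in 25 of 26 (median 1.49, adjusted p = 1.34e-17, adjusted p = 0.0796 with an estimated correlation), with *Gbp3* (2.84), *Oasl2* (2.28) and *Rsad2* (2.23) in front. The same was true of the A1 list (7 rose and 1 fell of 12, median 0.64, adjusted p = 0.000294, then 0.0962). Matrix protease and remodelling genes had 12 rises and 2 falls of 21, 12 and 3 over the list alone (median 0.47, adjusted p = 8.52e-06, then 0.0891), with *Mmp3* at 4.90. Prostaglandin, nitric oxide and oxylipin enzymes had 8 rises of 12 (1.45, adjusted p = 7.09e-07, then 0.0832). Astrocyte homeostatic genes had 19 falls and 1 rise of 30, 20 and 1 over the list alone (−0.32, adjusted p = 1.96e-07, then 0.0958), including *Slco1c1* (−1.57), *Kcnj10* (−1.16) and *Slc4a4* (−0.82). Cytosolic ribosomal protein genes, kept as an RNA quality list, rose in 42 of 48, 44 over the list alone (0.22, adjusted p = 1.4e-13, then 0.0891). Integrated stress response genes had 10 rises and 3 falls of 22 (0.23, adjusted p = 0.0138, then 0.424), with *Cebpb* (2.22) and *Nupr1* (1.74) up and *Slc3a2* (−0.47) down. NRF2 and antioxidant genes had 10 rises and 4 falls of 26 (0.03, adjusted p = 0.0356, then 0.3), with *Slc7a11* at 2.78. Aryl hydrocarbon receptor targets had 3 rises of 5 (0.21, adjusted p = 0.0298, then 0.0962). Subunits of complexes II, IV and V had 8 falls of 28, 6 over the list alone (−0.08, adjusted p = 0.0382, then 0.634). LXR and fatty acid synthesis genes had 6 falls and 2 rises of 14 (−0.13, adjusted p = 0.0389, then 0.283), with *Scd1* (−0.71) and *Scd2* (−0.70).

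Lists not called in experiment 1 are given with their camera adjusted p. Complex I subunits had 8 falls of 36, 4 over the list alone (adjusted p = 0.0695), and complex III subunits 4 of 9, 5 over the list alone (0.105). Mitochondrially encoded mRNAs had none of 7 (0.67). Glycolysis and lactate transport genes had 4 rises and 7 falls of 21 (0.497), and immediate early genes 11 rises and 8 falls of 24, 11 and 9 over the list alone (0.101). Cholesterol biosynthesis and uptake genes had 1 rise and 8 falls of 24 (0.16), and complement genes 2 rises and 1 fall of 9 (0.194). Hypoxia-inducible factor targets had 4 rises and 5 falls of 16 (median and mean 0.05, test direction down, adjusted p = 0.987). Cell cycle genes had 1 rise and 3 falls of 24 (0.277). Heat shock and unfolded protein response genes had 1 rise and 1 fall of 15 (median −0.02, mean 0.00, test direction up, adjusted p = 0.984). Among markers of other cells, microglia and macrophage genes had 3 falls of 18 (0.67), oligodendrocyte lineage genes 1 rise and 3 falls of 6 (0.16), fibroblast and mural genes 1 rise and 2 falls of 11 (0.791), and ependymal and choroid plexus genes 2 falls of 7 (0.494). Neuron (1 rise and 2 falls of 4) and endothelial markers (1 rise and 1 fall of 4) had too few measured genes for a test.

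In experiment 2 the same genes led. *Cxcl1* rose from 0.849 ± 0.461 to 793 ± 54.8 FPKM (n = 3 per group; log2 fold change 8.78, SE 0.146, limma adjusted p = 3.04e-14). *Lcn2* rose from 18.4 ± 1.15 to 1878 ± 47.7 FPKM (6.60, SE 0.0999, adjusted p = 2.13e-14), followed by *Steap4* (6.59), *Ccl7* (6.13), *Ccl2* (6.05), *Cxcl2* (5.70), *Ccl20* (5.36), *Cxcl10* (5.30), *Ptx3* (4.92) and the acute phase gene *Saa3* (4.87). *Nr4a3* (−2.00), *Ppp1r3c* (−1.91), *Tmem100* (−1.90), *Dio2* (−1.78), *Nr4a1* (−1.74), *Tsc22d3* (−1.63), *Wscd2* (−1.48), *Fam107a* (−1.40) and *Slc38a3* (−1.39) fell. *Gfap* (−0.25) and *Vim* (−0.21) fell again. *Hmox1* (0.17, adjusted p = 0.0898), *Nqo1* (−0.12) and *Slc1a2* (0.00) were not called. A U6 small nuclear RNA gene (ENSMUSG00000119376, chromosome 15, 72127199 to 72127305) was listed at 0 in all 3 IL-1α libraries and at 75.1, 131 and 54.9 in vehicle (adjusted p = 0.025). Other libraries go against an IL-1α effect on it: it was listed at 189 and 68.7 in 2 libraries with IL-1α plus S1QEL and at 113 in 1 with IL-1α plus S3QEL, and in experiment 1 at 59.1 and 18.8 in 2 IL-1α libraries and at 0 in 1 vehicle library. In all, 2381 genes rose and 2700 fell of 12830 tested, 1086 by at least 1.5-fold, and groups did not overlap for 48.1%.

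Of the lists in experiment 2, 19 were called and 9 kept the call with an estimated correlation. The 9 were NF-κB (23 rose and 1 fell of 25, 24 and 1 over the list alone, median 2.1, adjusted p = 1.91e-23), chemokines (16 and 1 of 17, 2.5, 1.01e-17), cytokines (13 and 1 of 16, 1.40, 1.48e-09), STAT3 targets (19 and 1 of 24, 0.82, 5.01e-14), interferon-stimulated genes (28 of 29, 1.32, 6.02e-21), pan-reactive genes (9 and 2 of 12, 1.07, 7.23e-08), the A2 list (7 and 2 of 11, 0.61, 0.000232), prostaglandin enzymes (8 and 1 of 11, 1.52, 1.12e-06) and homeostatic genes (1 and 19 of 28, −0.32, 1.07e-07). MHC class I genes (16 of 17, mean 1.11, adjusted p = 5.01e-14) reached adjusted p = 0.0555 with an estimated correlation and ribosomal protein genes (38 of 48, 44 over the list alone, 0.22, 1.01e-09) 0.286. Oligodendrocyte lineage markers had 3 falls of 5 (−0.40, adjusted p = 0.018, then 0.0672), namely *Olig1* (−0.87), *Olig2* (−0.85) and *Cnp* (−0.40). The A1, complement, matrix, stress response, cholesterol, LXR and complex II, IV and V lists were also called, with adjusted p from 0.000232 to 0.0429, and lost the call (adjusted p from 0.158 to 0.608 with an estimated correlation). Across 12337 genes tested in both experiments, the IL-1α fold changes had a Pearson r of 0.884 and a Spearman rho of 0.827. There were 1656 genes that rose in both (393 expected by chance), 1927 that fell in both (545 expected) and 2 with opposite calls. Genes are not independent replicates, so no p-value is given for these correlations. The tables were normalized separately, and each test therefore stays within an experiment.

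**Figure D1:**
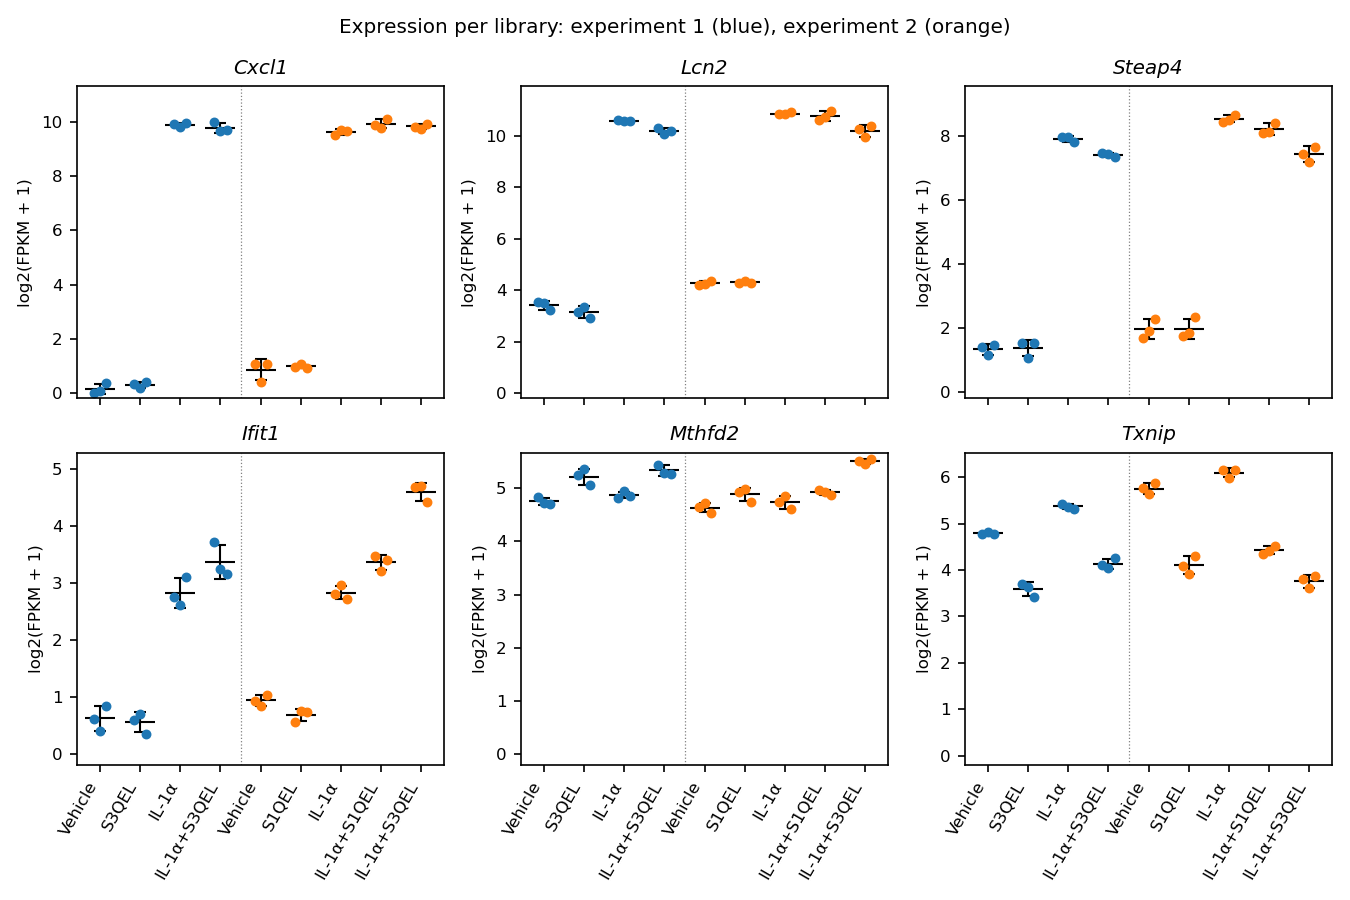
Expression of *Cxcl1*, *Lcn2*, *Steap4*, *Ifit1*, *Mthfd2* and *Txnip* as log2(FPKM + 1) for each library in the 9 groups, with mean and SD. Blue points are experiment 1 and orange points experiment 2.

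S3QEL1.2 (3 µM), which suppresses electron leak at site IIIQo of complex III, was set against vehicle to see its effect on unstimulated astrocytes, where it lowered *Txnip*. *Txnip* (ENSMUSG00000038393, chromosome 3, 96465273 to 96469199), which encodes a thioredoxin-binding protein that limits glucose uptake, fell from 26.7 ± 0.591 to 11.1 ± 1.17 FPKM (n = 3 per group; log2 fold change −1.21, SE 0.0725, limma adjusted p = 2.84e-05). *Dio2* rose from 57.3 ± 5.9 to 101 ± 13.3 FPKM (0.81, SE 0.124, adjusted p = 0.035). *Mthfd2* (ENSMUSG00000005667, chromosome 6, 83282673 to 83302890), which encodes a mitochondrial enzyme of folate metabolism, rose from 26 ± 1.4 to 36.4 ± 3.86 FPKM (0.47, SE 0.0752, adjusted p = 0.0372). The amino acid transporter gene *Slc3a2* rose from 219 ± 4.2 to 291 ± 14.7 FPKM (0.40, SE 0.0452, adjusted p = 0.0107). *Lncpint* (0.78), *Nr4a3* (0.74), *Gprc5a* (0.71), *Dlk1* (0.62), *Bud13* (0.59), *Ptx3* (0.47), *Nfil3* (0.46), *Cebpb* (0.39), *Dnajb9* (0.32) and *Atf5* (0.23) rose too. Falls besides *Txnip* were small: *Cdon* (−0.31), *Chst2* (−0.31), *Syt11* (−0.28), *Abr* (−0.27), *Phkb* (−0.26), *Mgat5* (−0.25), *Tom1l2* (−0.21) and *Zcchc24* (−0.20). In all, 27 genes rose and 10 fell of 12780, 10 by at least 1.5-fold, and groups did not overlap for 16.7%. These calls depend on every library: leaving out vehicle library 1, 2 or 3 left 5, 7 or 1 genes, and leaving out S3QEL library 1, 2 or 3 left 15, 4 or 6. Of the 22 genes named here or in a list that were called, 1 kept its call under every alternative.

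Integrated stress response genes rose most as a list with S3QEL alone: 4 of 22 were called, 16 over the list alone (median 0.28, camera adjusted p = 1.26e-14, adjusted p = 0.203 with an estimated correlation). Heat shock and unfolded protein response genes had 1 rise of 15, 3 over the list alone (0.20, adjusted p = 1.32e-06, then 0.498). Immediate early genes had 1 rise of 24, 8 over the list alone (0.13, adjusted p = 1.05e-05, then 0.49). NRF2 genes had 0 rises of 26, 5 over the list alone (0.03, adjusted p = 0.019, then 0.498), and ribosomal protein genes 0 of 48 (0.06, adjusted p = 5.16e-07, then 0.498). These 5 were the only lists called, and none kept its call. Microglia and macrophage markers were not called (0 of 18, 17 of them above 0, median 0.16, adjusted p = 0.112, then 0.907), nor were they during IL-1α (0 of 18, 16 above 0, 0.08, adjusted p = 0.224, then 0.845). NF-κB targets (median 0.01, mean −0.02, test direction up) and interferon-stimulated genes (median −0.04, mean 0.01, test direction up) both had adjusted p = 0.981.

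The comparison of IL-1α plus S3QEL with IL-1α asks which parts of the inflammatory response change with S3QEL. The data hold RNA alone and no measure of electron leak. In experiment 1 S3QEL again lowered *Txnip*, from 40.3 ± 1.47 to 16.6 ± 1.34 FPKM (n = 3 per group; log2 fold change −1.24, SE 0.0725, limma adjusted p = 2.19e-05). The lactate dehydrogenase gene *Ldha* fell from 383 ± 6.39 to 306 ± 5.66 FPKM (−0.32, SE 0.0354, adjusted p = 0.00563). *Cxcl5* (ENSMUSG00000029371, chromosome 5, 90907219 to 90909483), another neutrophil chemokine gene, fell from 20.9 ± 4.55 to 10.4 ± 2.05 FPKM (−0.94, SE 0.163, adjusted p = 0.0456). *Mthfd2* rose from 28.3 ± 1.26 to 39.4 ± 2.72 FPKM (0.46, SE 0.0752, adjusted p = 0.0365). *Dio2* (0.83), *Dlk1* (0.63), the growth factor receptor gene *Met* (0.53), *Cobll1* (0.53), *Dnajb9* (0.37), *Bri3* (0.35), *Slc7a1* (0.33), *Slc38a2* (0.31) and *Trim56* (0.28) rose. *Sorbs1* (−0.54), *Cdon* (−0.34), *Syt11* (−0.33), *Etv5* (−0.30), *Lix1l* (−0.29), *Nr2e1* (−0.26) and *Abr* (−0.24) fell. Most genes that lead the IL-1α response were not called: *Cxcl1* (−0.11, 95% interval −0.34 to 0.11), *Ccl2* (0.06), *Il6* (−0.05), *Cxcl10* (−0.04), *Nfkbia* (−0.05), *Lcn2* (−0.41, adjusted p = 0.143), *Steap4* (−0.49, adjusted p = 0.113), *C3* (−0.31, adjusted p = 0.263), *Stat3* (−0.14, adjusted p = 0.098) and *Hmox1* (0.34, adjusted p = 0.0844). In all, 16 genes rose and 14 fell of 12780, 5 by at least 1.5-fold, and groups did not overlap for 19%. Leaving out IL-1α library 1, 2 or 3 left 2, 11 or 12 calls, and leaving out IL-1α plus S3QEL library 1, 2 or 3 left 22, 11 or 8. Of the 20 genes named here or in a list that were called, 1 kept its call under every alternative.

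Interferon-stimulated genes had a median log2 fold change of 0.19 with S3QEL during IL-1α in experiment 1, with 0 of 26 called and 1 over the list alone (camera adjusted p = 7.04e-08, adjusted p = 0.374 with an estimated correlation). *Rsad2*, which encodes the antiviral enzyme viperin, was the closest single gene (0.79, adjusted p = 0.0549). Heat shock and unfolded protein response genes (1 rise of 15, 5 over the list alone, median 0.20, adjusted p = 4.34e-08), integrated stress response genes (1 of 22, 12 rises and 2 falls over the list alone, 0.15, adjusted p = 1.33e-06) and immediate early genes (0 of 24, 4 over the list alone, 0.08, adjusted p = 0.00396) shifted up. Pan-reactive genes (0 of 12, 5 falls over the list alone, −0.17, adjusted p = 0.00438), STAT3 targets (0 of 24, 5 falls over the list alone, −0.07, adjusted p = 0.0346), glycolysis genes (1 fall of 21, 3 over the list alone, −0.08, adjusted p = 0.000557), complex I subunits (0 of 36, −0.07, adjusted p = 0.00166), complex II, IV and V subunits (0 of 28, −0.06, adjusted p = 0.0396) and oligodendrocyte markers (0 of 6, 1 fall over the list alone, −0.12, adjusted p = 0.0346) shifted down. All 10 lists lost the call with an estimated correlation, with adjusted p from 0.286 to 0.796.

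No gene passed limma for a different S3QEL effect with and without IL-1α in experiment 1 (0 of 12780 called, 758 at unadjusted p below 0.05, 639 expected by chance). The smallest p-values belonged to the long noncoding RNA gene *Gm47766* (0.66, SE 0.12), the peptidyl-prolyl isomerase gene *Fkbp3* (−0.26, SE 0.0505) and a microRNA gene (ENSMUSG00002076169, chromosome 6, 136785541 to 136785681), each with adjusted p = 0.564. The microRNA gene was listed at 0 in every vehicle and IL-1α plus S3QEL library at 4.67, 2.88 and 2.56 in the IL-1α libraries, and at 2.47, 0 and 2.51 with S3QEL alone, so it varied between 0 and detection within a group. *Cxcl5* (−0.98, SE 0.231, adjusted p = 0.761) and *Ldha* (−0.25, SE 0.05, adjusted p = 0.564) had negative interactions that were not called. Of the lists, 10 were called and none with an estimated correlation. Interferon-stimulated genes shifted up (median 0.23, camera adjusted p = 8.66e-06, then 0.522). Members near 0 without IL-1α limit this result, since the pseudocount of 1 makes their changes small there. *Ifit1*, for one, was at 0.321 to 0.79 FPKM in vehicle. Chemokines (−0.25, adjusted p = 0.0189), STAT3 targets (−0.13, 0.000351), pan-reactive genes (−0.11, 0.0202), complex I (−0.12, 1.14e-05), complexes II, IV and V (−0.09, 0.00034), glycolysis (−0.08, 8.24e-05), stress response (−0.11, 0.00492), hypoxia (−0.13, 0.0295) and ribosomal protein genes (−0.08, 8.58e-08) shifted down.

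S1QEL2.2 (10 µM), which suppresses electron leak at site IQ of complex I, was given in experiment 2 and also lowered *Txnip*, from 53.1 ± 4.38 to 16.3 ± 2.33 FPKM in unstimulated cells (n = 3 per group; log2 fold change −1.65, SE 0.0972, limma adjusted p = 2.52e-06). *Arrdc4*, a relative of *Txnip* in the α-arrestin family, fell from 7.35 ± 1.03 to 4.04 ± 0.668 FPKM (−0.73, SE 0.0998, adjusted p = 0.00953), and the cholesterol exporter gene *Abca1* fell (−0.41, SE 0.064, adjusted p = 0.0188). *Ccl3* (ENSMUSG00000000982, chromosome 11, 83538670 to 83540181), which encodes a chemokine for myeloid cells, rose from 3.05 ± 0.268 to 5.95 ± 0.542 FPKM (0.78, SE 0.0885, adjusted p = 0.00226). *Dio2* (0.56, adjusted p = 0.00628), *Nxph3* (0.46), *Flcn* (0.40), *Ak5* (0.36), the V-ATPase subunit gene *Atp6v1b2* (0.32), *Snx8* (0.28), *Nectin2* (0.25), *Agap3* (0.21) and *Sqstm1* (0.17) rose. In all, 13 genes rose and 3 fell of 12830, 5 by at least 1.5-fold, and groups did not overlap for 12%. The count fell to 10 without vehicle library 1 and to 6 and 9 without S1QEL libraries 1 and 2. Of the 13 called genes that the rule names, 1 kept its call under every alternative. Immediate early genes (0 of 24 called, 6 over the list alone, median 0.18, camera adjusted p = 1.07e-07), integrated stress response genes (0 of 22, 3 over the list alone, 0.11, 3.64e-06), cholesterol genes (0 of 24, 3 over the list alone, 0.08, 0.00049), ribosomal protein genes (0 of 48, 0.05, 0.00049), NRF2 genes (1 rise of 26, 3 over the list alone, 0.02, 0.00613) and the A2 list (0 of 11, 2 over the list alone, 0.03, 0.0338) shifted up. Interferon-stimulated genes (0 of 29, −0.14, 8.04e-06) and mitochondrially encoded mRNAs (0 of 7, −0.15, 0.0154) shifted down. All 8 lists lost the call with an estimated correlation (adjusted p from 0.274 to 0.898).

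The matching comparison for S1QEL is IL-1α plus S1QEL with IL-1α. S1QEL lowered *Txnip* from 67.6 ± 4.59 to 20.5 ± 1.31 FPKM (n = 3 per group; log2 fold change −1.67, SE 0.0972, limma adjusted p = 1.07e-06). It raised *Csf2* (ENSMUSG00000018916, chromosome 11, 54138097 to 54140493), which encodes the growth factor GM-CSF, from 12.8 ± 1.24 to 21.8 ± 4.06 FPKM (0.71, SE 0.115, adjusted p = 0.015). *Csf3*, which encodes G-CSF, rose from 20 ± 2.53 to 30.4 ± 2.83 FPKM (0.58, SE 0.0778, adjusted p = 0.00423), and *Lif* rose (0.54, SE 0.0914, adjusted p = 0.0212). *Ccl3* (0.70), *Mylk2* (0.68), *Ifit3* (0.58), *Rsad2* (0.53), *Ifit1* (0.53), *Lgals3* (0.51), *Hmga1* (0.49), *Fosl1* (0.49), *Hmox1* (0.40, adjusted p = 0.0319), *Zfp36* (0.33) and *Sqstm1* (0.25) rose. *Pfkl*, which encodes liver phosphofructokinase, fell from 35.9 ± 1.47 to 25.8 ± 1.32 FPKM (−0.46, SE 0.0577, adjusted p = 0.00281). *Narf* (−0.52), the oxygen-sensing prolyl hydroxylase gene *Egln3* (−0.51), *Abca1* (−0.44), *Ak4* (−0.41), *Cdon* (−0.35), *Naa10* (−0.32), *Ciapin1* (−0.30), *Kdm3a* (−0.28), *Timp3* (−0.24) and *Ldha* (−0.23) fell. A U6 small nuclear RNA gene (ENSMUSG00000119738, chromosome 3, 88877930 to 88878036) was listed at 0 in all 3 libraries with S1QEL and at 138, 68.3 and 107 with IL-1α alone (adjusted p = 9.77e-07), but in experiment 1 at 0 in every library with IL-1α and also in 1 vehicle and 2 S3QEL libraries. *Cxcl1* (0.30, adjusted p = 0.511), *Ccl2* (0.32, adjusted p = 0.472) and *Lcn2* (−0.09, adjusted p = 0.811) were not called. In all, 37 genes rose and 19 fell of 12830, 7 by at least 1.5-fold, and groups did not overlap for 17.8%. Leaving out IL-1α library 1, 2 or 3 left 15, 32 or 17 calls, and leaving out IL-1α plus S1QEL library 1, 2 or 3 left 19, 26 or 37. Of the 27 called genes that the rule names, 3 kept the call under every alternative.

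Among lists with S1QEL during IL-1α, interferon-stimulated genes had 3 rises of 29, 7 over the list alone (median 0.22, camera adjusted p = 4.35e-13, adjusted p = 0.163 with an estimated correlation). Cytokine genes had 3 rises of 16, 5 over the list alone (0.14, 4.79e-07, then 0.114). Immediate early genes had 2 rises of 24, 3 over the list alone (0.13, 3.52e-06, then 0.163). Chemokine genes had 1 rise of 17, 4 rises and 1 fall over the list alone (0.07, 0.00171, then 0.387). Hypoxia-inducible factor targets had 2 falls of 16, 6 falls and 1 rise over the list alone (−0.13, 0.00205, then 0.114). Glycolysis genes had 2 falls of 21, 5 falls and 2 rises over the list alone (−0.06, 0.018, then 0.473). NRF2 genes had 2 rises of 26 (0.05, 0.0021, then 0.329), and matrix genes 1 fall of 20, 2 rises and 1 fall over the list alone (0.09, 0.00603, then 0.387). Cholesterol (0.09, 7.91e-06), A2 (0.05, 0.00313), stress response (0.07, 0.00509), MHC class I (0.05, 0.0113), heat shock and unfolded protein (0.10, 0.0113), mitochondrially encoded (0.10, 0.0222) and neuron marker genes (0.13, 0.0241) shifted up with 0 called. Cell cycle genes (−0.08, 0.0223) and oligodendrocyte markers (−0.13, 0.031) shifted down with 0 called. None of these 17 lists kept the call (highest adjusted p = 0.678 with an estimated correlation).

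S3QEL during IL-1α in experiment 2 raised interferon-stimulated genes most. *Ifit1* (ENSMUSG00000034459, chromosome 19, 34618271 to 34627409), which encodes an RNA-binding antiviral protein, rose from 6.1 ± 0.586 to 23.2 ± 2.56 FPKM (n = 3 per group; log2 fold change 1.77, SE 0.099, limma adjusted p = 2.15e-07). *Rsad2* (ENSMUSG00000020641, chromosome 12, 26492745 to 26506451) rose from 8.98 ± 0.973 to 30.7 ± 4.06 FPKM (1.66, SE 0.101, adjusted p = 4.71e-07), with *Ifit3* (1.53), *Usp18* (1.43), *Ifit3b* (1.38) and *Rtp4* (1.23). The substance P receptor gene *Tacr1* (1.47), the glutathione-degrading enzyme gene *Chac1* (1.43), *Lgals3* (1.34) and *AA467197* (1.19) complete the 10 largest rises. *Txnip* fell from 67.6 ± 4.59 to 12.6 ± 1.28 FPKM (−2.34, SE 0.0972, adjusted p = 2.77e-08). *Steap4* fell from 372 ± 27.5 to 174 ± 29.6 FPKM (−1.11, SE 0.175, adjusted p = 0.000681), and *Lcn2* from 1878 ± 47.7 to 1190 ± 181 FPKM (−0.67, SE 0.0999, adjusted p = 0.000476). *Cxcl5* (−1.25), *Saa3* (−1.17), *Nos2* (−1.01), *Gas1* (−0.90), *Angptl4* (−0.86), *Pdk4* (−0.78), *Arrdc3* (−0.77) and *Jarid2* (−0.76) fell. Of the IL-1α response genes, *Aqp4* (−0.51), *C3* (−0.41, adjusted p = 0.0153), *Serpina3n* (−0.31), *Vcam1* (−0.20) and *Stat3* (−0.19, adjusted p = 0.000588) fell, as did *Gfap* (−0.25). *Hmox1* rose (0.79, adjusted p = 1.49e-05), and *Ccl2* rose further (0.48, adjusted p = 0.0318). *Cxcl1* (0.20, adjusted p = 0.36), *Il6* (−0.16, adjusted p = 0.268), *Cxcl10* (0.10, 95% interval −0.31 to 0.51), *Nfkbia* (0.12, adjusted p = 0.381), *Icam1* (0.05), *Ptgs2* (0.08), *Socs3* (−0.15, adjusted p = 0.0518), *Vim* (−0.05), *Nqo1* (−0.12) and *Slc1a2* (−0.12) were not called. In all, 1458 genes rose and 1310 fell of 12830, 215 by at least 1.5-fold, and groups did not overlap for 38.5%.

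Interferon-stimulated genes rose in 25 of 29 with S3QEL during IL-1α in experiment 2 (median log2 fold change 0.73, camera adjusted p = 1.87e-21, adjusted p = 0.146 with an estimated correlation). Integrated stress response genes had 14 rises and 1 fall of 22, 14 and 2 over the list alone (0.31, adjusted p = 1.97e-07, then 0.146), including *Mthfd2* (25.7 ± 2.28 to 44.4 ± 1.45 FPKM, 0.77, SE 0.0708, adjusted p = 1.32e-05), *Slc3a2* (0.68) and *Sesn2* (0.67). Heat shock and unfolded protein response genes had 11 rises of 14, 13 over the list alone (0.35, 6.88e-07, then 0.339), with *Dnajb9* at 0.63. Immediate early genes had 12 rises of 24, 13 over the list alone (0.30, 3.73e-06, then 0.24), with *Nr4a1* (1.179), *Fosl1* (0.83) and *Myc* (0.73). MHC class I genes had 8 rises of 17, 9 over the list alone (0.17, 0.000662, then 0.474), with *Tap1* (0.62) and *H2-K1* (0.31). Cytokine genes had 7 rises of 16 (0.09, 0.0182, then 0.44), with *Il11* (1.00), *Il23a* (1.00), *Csf3* (0.78) and *Clcf1* (0.38). STAT3 targets had 9 falls of 24, 11 over the list alone (−0.10, 0.00734, then 0.239). Pan-reactive genes had 7 falls and 2 rises of 12 (−0.28, 0.0323, then 0.339), with *Cp* at −0.31. Glycolysis genes had 8 falls and 2 rises of 21 (−0.09, 0.0182, then 0.474), as *Pfkl* (−0.70) and *Ldha* (−0.49) fell while *Eno2* (0.78) and *Hk2* (0.53) rose. Cholesterol genes had 8 falls of 24, 8 falls and 2 rises over the list alone (−0.06, 0.0467, then 0.822), with *Nsdhl* at −0.35. LXR genes had 6 falls of 14, 7 over the list alone (−0.11, 0.018, then 0.31), and cell cycle genes 2 falls of 24, 1 over the list alone (−0.09, 0.0469, then 0.822). Oligodendrocyte markers had 3 falls of 5 (−0.24, 0.016, then 0.15), in *Olig2* (−0.71), *Olig1* (−0.63) and *Cnp* (−0.24). NF-κB targets had 3 falls of 25 and were not called (median 0.00, mean −0.01, test direction up, adjusted p = 0.925), nor were chemokines (4 rises and 2 falls of 17, 0.04, adjusted p = 0.716) or NRF2 genes (6 rises and 2 falls of 26, median −0.01, mean 0.06, test direction up, adjusted p = 0.425).

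**Figure D2:**
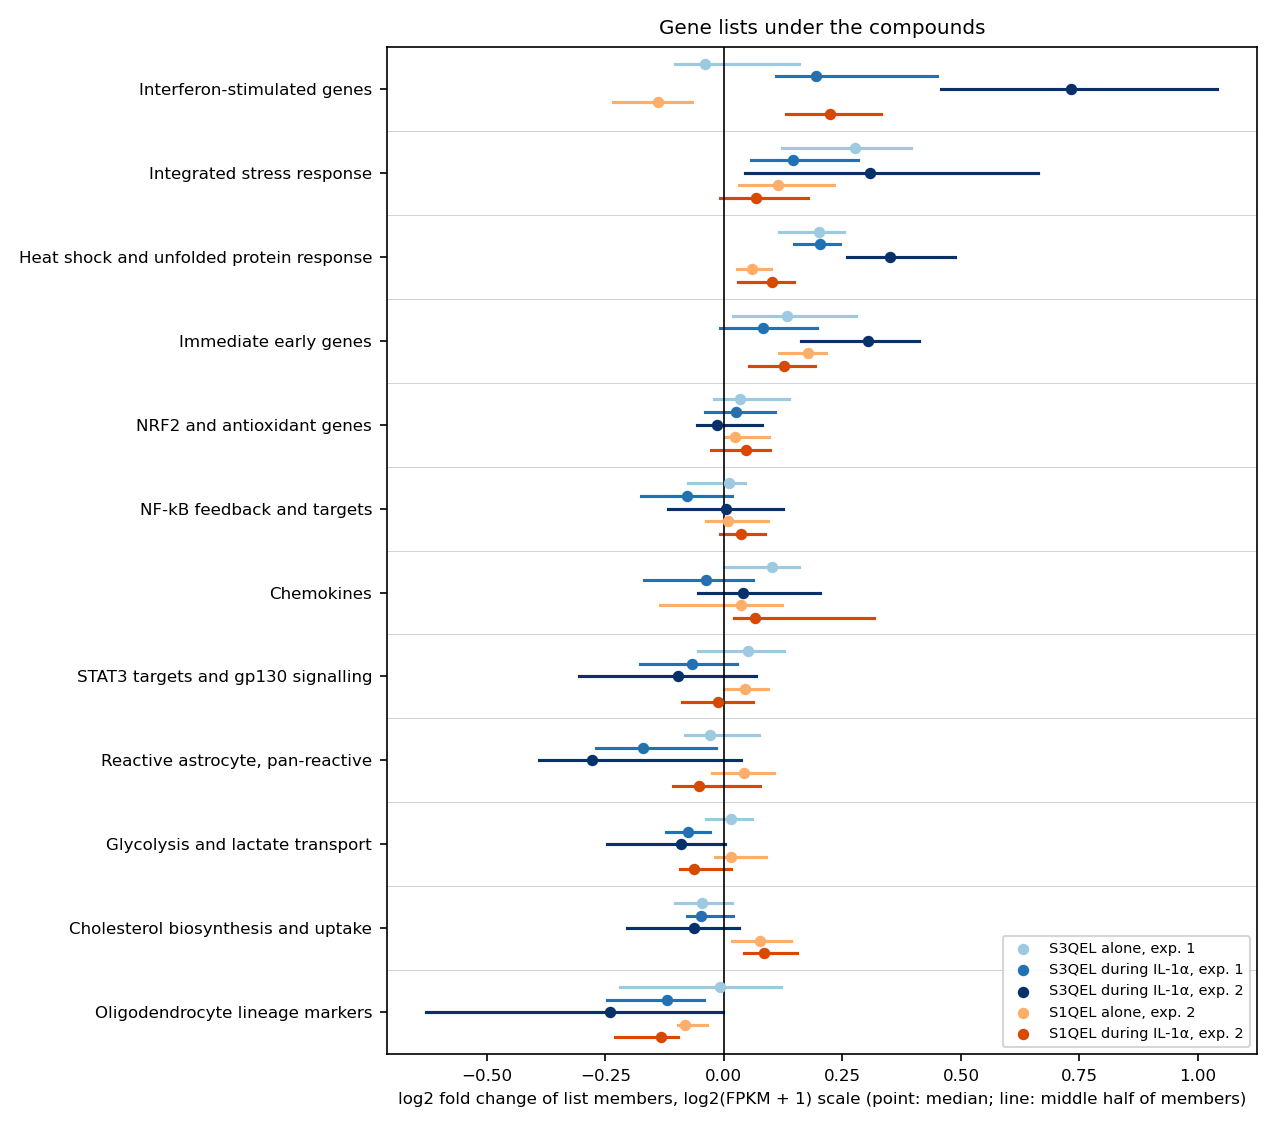
Median log2 fold change (point) and interquartile range of the members (line) of 12 gene lists fixed before the data were examined, in the 5 contrasts of a compound against its own control.

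Setting S3QEL against S1QEL during IL-1α asks whether the compounds differ at the doses used. *Ifit1* was higher with S3QEL, at 23.2 ± 2.56 against 9.28 ± 0.935 FPKM (n = 3 per group; log2 fold change 1.24, SE 0.099, limma adjusted p = 2.01e-05). *Rsad2* (1.13), *Chac1* (1.07), *Usp18* (1.03), *Ifit3* (0.95), the stress cytokine gene *Gdf15* (0.91), *Rtp4* (0.90), *Ifit3b* (0.90), *Lgals3* (0.83) and *Hmox1* (0.39) were higher with S3QEL. *Steap4* was lower, at 174 ± 29.6 against 299 ± 37.6 FPKM (−0.79, SE 0.175, adjusted p = 0.0157), as was *Lcn2*, at 1190 ± 181 against 1769 ± 230 FPKM (−0.58, SE 0.0999, adjusted p = 0.00475). *mt-Nd6* (ENSMUSG00000064368, mitochondrial genome, 13552 to 14070) stood at 59 ± 13.6 against 152 ± 60.7 FPKM (−1.29, SE 0.263, adjusted p = 0.0113). However, 0 of 7 mitochondrially encoded mRNAs were called with S3QEL or with S1QEL against IL-1α alone. As a list they were not called between the compounds (camera adjusted p = 0.235). *Cxcl5* (−1.02), *Nos2* (−0.92), *Saa3* (−0.85), *Nkain2* (−0.74), *Fgf1* (−0.73), *Txnip* (−0.67), *Pdk4* (−0.63), *Mro* (−0.61), *Timp1* (−0.60), *Aqp4* (−0.44), *Gfap* (−0.21) and *Stat3* (−0.12) were lower. *Cxcl1* (−0.10, 95% interval −0.41 to 0.22), *Ccl2* (0.17, −0.15 to 0.48), *Nfkbia* (−0.02, −0.21 to 0.18), *Icam1* (0.03, −0.10 to 0.16), *Cxcl10* (0.03, −0.38 to 0.45) and *Il6* (−0.27, −0.47 to −0.06, adjusted p = 0.109) were not called. The U6 gene was at 117 ± 23.1 FPKM with S3QEL and listed at 0 with S1QEL. In all, 626 genes were higher and 474 lower of 12830, 63 by at least 1.5-fold, and groups did not overlap for 29.3%. With any single library of these groups left out, 479 to 704 were called (fewest without IL-1α plus S1QEL library 1). Of the 55 called genes that the rule names, 29 kept the call under every alternative. The doses were 3 µM for S3QEL and 10 µM for S1QEL, so dose and compound are not separated.

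As lists, interferon-stimulated genes were higher with S3QEL than with S1QEL in 20 of 29, 26 over the list alone (median 0.50, camera adjusted p = 9.79e-21, adjusted p = 0.107 with an estimated correlation). Stress response genes (11 higher and 1 lower of 22, 15 and 1 over the list alone, 0.26, 5.44e-09), heat shock and unfolded protein genes (7 of 14, 11 over the list alone, 0.27, 2.58e-07), immediate early genes (8 of 24, 9 over the list alone, 0.16, 0.00223) and MHC class I genes (2 of 17, 4 over the list alone, 0.15, 0.00928) were also higher. STAT3 targets (9 lower of 24, 11 over the list alone, −0.10, 0.000166), pan-reactive genes (5 lower and 1 higher of 12, 6 and 1 over the list alone, −0.17, 0.00928), cholesterol genes (7 of 24, 12 over the list alone, −0.17, 4.12e-09) and matrix genes (2 of 20, −0.10, 0.00223) were lower. So were oligodendrocyte markers (2 of 5, 3 over the list alone, −0.14, 0.0105), aryl hydrocarbon receptor targets (0 of 5, −0.27, 0.0258), homeostatic genes (4 lower and 1 higher of 28, 5 and 1 over the list alone, −0.02, 0.0395), chemokines (2 of 17, 3 over the list alone, −0.08, 0.0401) and LXR genes (3 of 14, −0.05, 0.0488). All 14 lost the call with an estimated correlation (lowest adjusted p = 0.107).

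Whether S1QEL acts differently with and without IL-1α was tested in experiment 2, and the U6 gene ENSMUSG00000119738 was the only gene called (limma adjusted p = 1.73e-05, 473 genes at unadjusted p below 0.05, 641.5 expected by chance). *Ifit1* (0.79, SE 0.14), *Ifit3* (0.65, SE 0.107) and *Csf3* (0.59, SE 0.11) came next, each with adjusted p = 0.206. *Ifit1* was at 0.791 to 1.047 FPKM in vehicle, where the pseudocount of 1 makes changes small, so its interaction depends on that setting. Interferon-stimulated genes shifted up as a list (median 0.34, camera adjusted p = 9.08e-28, adjusted p = 0.0685 with an estimated correlation). So did cytokines (0.14, adjusted p = 8.55e-06), the A1 list (0.12, 0.0234), MHC class I genes (0.11, 0.0234), mitochondrially encoded mRNAs (0.27, 8.55e-06), matrix genes (0.08, 0.0174) and neuron markers (0.12, 0.0234). STAT3 targets (−0.07, 0.0376), glycolysis (−0.08, 0.00113), hypoxia (−0.12, 0.00113), ribosomal protein (−0.06, 9.61e-05) and ependymal marker genes (−0.32, 0.0357) shifted down. None of the 12 kept the call.

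*Txnip*, *Cxcl5*, *Ldha*, *Sorbs1*, *Mthfd2*, *Met* and *Dlk1* were called in the same direction with S3QEL during IL-1α in both experiments. Of the 29 genes called in experiment 1 and tested in both, 26 were called in experiment 2 with the same sign, 13 up (1.74 expected) and 13 down (1.47 expected). Leaving out a library of experiment 1 cut these shared calls to 2, 10 and 11 (IL-1α libraries 1, 2 and 3) and to 20, 7 and 7 (IL-1α plus S3QEL libraries 1, 2 and 3), and leaving out one of experiment 2 gave 25 or 26. *Dio2*, *Bri3* and *Fjx1* (the last chosen after its values were seen) were called in experiment 1 alone, and whether these genes differ between experiments was not tested. Fold changes over all genes tested in both had a Pearson r of 0.386 and a Spearman rho of 0.469, and 86.5% of the experiment 2 calls had the same sign in experiment 1. S1QEL and S3QEL during IL-1α in experiment 2 shared 35 rises and 16 falls (13 to 53 calls in common with single libraries left out, fewest without IL-1α library 1), but both contrasts use the same IL-1α libraries, which alone can make calls coincide, so no expected count is given. Against 100 simulated draws of unchanged groups with that shared control, r was 0.5 (mean of the draws 0.494, highest 0.649), rho 0.619 (0.461, highest 0.477), the covariance 0.0338 (0.0186, highest 0.0272) and the share of genes with the same sign 72.5% (66.6%, highest 67.7%). The draws leave out noise that genes have in common, so these excesses are not a test. Without a shared library, S3QEL in experiment 1 and S1QEL in experiment 2, both during IL-1α, had 5 rises (0.0438 expected) and 4 falls (0.0216 expected) in common.

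**Figure D3:**
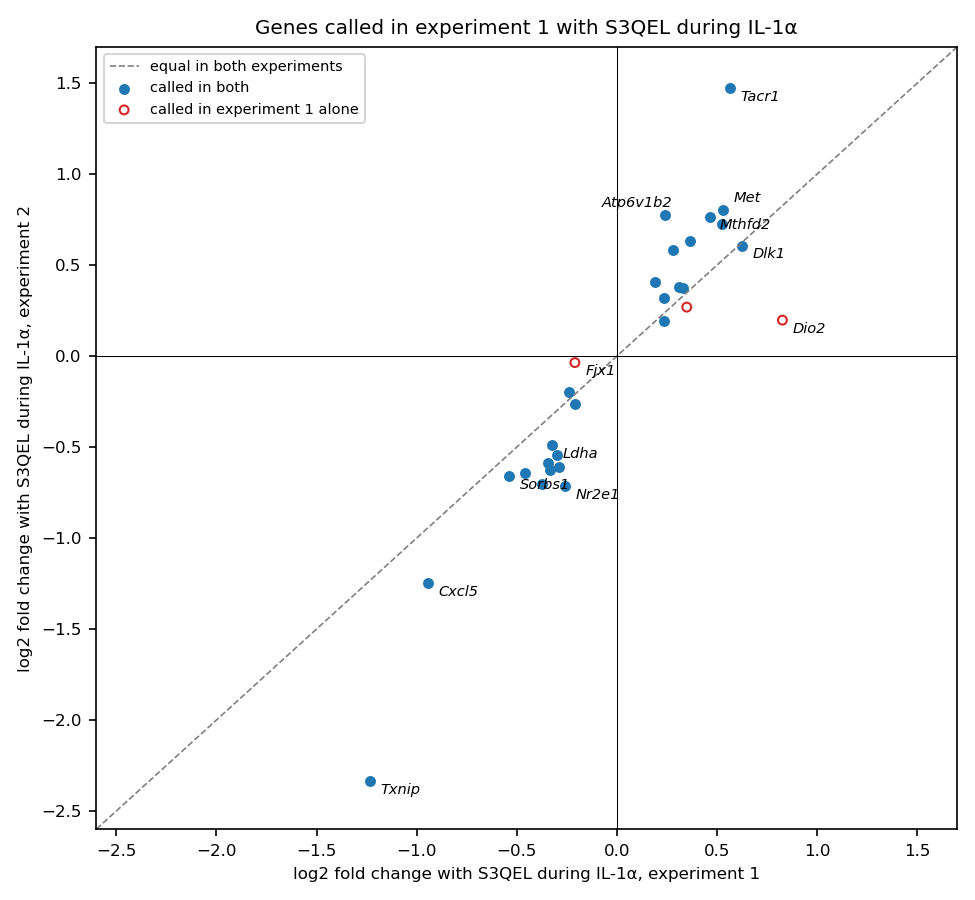
Log2 fold change with S3QEL during IL-1α in experiment 1 and experiment 2 for the 29 genes called in experiment 1 and tested in both. The dashed line marks equal change in both.

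Genes that IL-1α raised at least 2-fold, such as *Cxcl1*, *Lcn2* and *Steap4*, were taken as a set from the other experiment and tested with each compound. With S3QEL during IL-1α the 293 such genes of experiment 1 had a median log2 fold change of −0.04 (0 rose and 1 fell, camera adjusted p = 0.242), and the 306 in experiment 2 had 0.04 (78 rose and 46 fell, adjusted p = 0.0896). With S1QEL during IL-1α the 306 genes had a median of 0.06 (13 rose, adjusted p = 6.27e-12, adjusted p = 0.278 with an estimated correlation), which was 0.022 without IL-1α plus S1QEL library 3 and 0.102 without library 2 of that group, and S3QEL set against S1QEL gave −0.03 (36 higher and 37 lower, adjusted p = 0.0911). Genes that IL-1α lowered shifted further down with S3QEL in experiment 1 (72 genes, −0.09, adjusted p = 0.0315), though 1 rose and 0 fell singly. In experiment 2 they did so too (100 genes, −0.15, 10 rose and 37 fell, adjusted p = 0.000118). They also shifted down with S1QEL (−0.10, 2 fell, adjusted p = 0.000331). The same held for S3QEL set against S1QEL (−0.09, 7 higher and 14 lower, adjusted p = 0.00191). Each of these calls had adjusted p = 0.278 with an estimated correlation. Without IL-1α the raised set had a median of 0.02 with S3QEL (adjusted p = 0.262) and 0.01 with S1QEL (adjusted p = 0.291). Some of its genes lay near 0 there, where the pseudocount of 1 makes changes small. In vehicle libraries of experiment 1 *Cxcl1* was at 0 to 0.277 FPKM, though *Lcn2* was at 8.314 to 10.58. For genes near 0, these medians and the interactions cannot show whether a compound acts without IL-1α. The lowered set had −0.06 with S3QEL (adjusted p = 0.124) and −0.01 with S1QEL (test direction up, adjusted p = 0.588). For a different effect with and without IL-1α, the raised set had −0.06 for S3QEL (adjusted p = 0.0315, then 0.78), the lowered set −0.01 (adjusted p = 0.458), and S1QEL gave 0.05 for the raised set (adjusted p = 1.8e-08, then 0.278) and −0.06 for the lowered set (adjusted p = 3.14e-05, then 0.278). Single libraries also moved these medians. With S3QEL during IL-1α the raised set ranged from −0.0769 to −0.00204 in experiment 1 (without IL-1α plus S3QEL libraries 1 and 2). In experiment 2 it ranged from 0.00114 to 0.0632 (without IL-1α plus S3QEL libraries 3 and 2). For S3QEL against S1QEL it changed sign, from −0.0608 (without IL-1α plus S3QEL library 3) to 0.0112 (without IL-1α plus S1QEL library 3). Without IL-1α the raised set ranged from 0.00855 (without S3QEL library 1) to 0.0241 (without vehicle library 1) with S3QEL and from 0.00476 (without vehicle library 2) to 0.0216 (without S1QEL library 1) with S1QEL. The lowered set ranged from −0.086 (without vehicle library 1) to −0.0222 (without S3QEL library 2) with S3QEL, and with S1QEL it changed sign, from −0.0228 (without S1QEL library 3) to 0.00992 (without vehicle library 3). For a different effect with and without IL-1α, the lowered set with S3QEL ranged from −0.0697 (without IL-1α plus S3QEL library 2) to −0.0126 (without vehicle library 1). S1QEL gave a difference of 0.00927 for the raised set without IL-1α plus S1QEL library 3, S3QEL a difference of −0.0298 for the raised set without IL-1α plus S3QEL library 2, and the lowered set was at −0.0538 with S3QEL in experiment 1 without IL-1α plus S3QEL library 1 and at −0.0463 for S3QEL against S1QEL without IL-1α plus S3QEL library 3.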

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

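Every test of an explanation in this part was chosen after the result was seen, apart from the test that leaves out single libraries for the interferon-stimulated genes and the counts over other splits of the libraries.

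S3QEL during IL-1α called 2768 genes in experiment 2, with *Ifit1* and *Txnip* in front, and 30 in experiment 1. If only lower precision in experiment 1 were at work, effects would be of equal size and the slope of experiment 1 on experiment 2, corrected for noise, would be 1, but it was 0.366 (jackknife SE 0.0742). Of the 2728 genes called in experiment 2 and tested in both, 97.5% had the larger change there (median size 0.279 against 0.101), which in part follows from choosing genes by experiment 2. A single library of experiment 2 is also excluded as the cause, since the lowest count with 1 library left out was 2015. Differences between experiments in the cells, the compound or the handling stay open, because the labels give none of these and the experiments were not set against each other in a test.

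Interferon-stimulated genes such as *Ifit1*, *Rsad2* and *Ifit3* were higher with S3QEL during IL-1α in experiment 2 (median log2 fold change 0.733, adjusted p = 0.146 by camera with an estimated correlation, so the list was not called by that test). More microglia or macrophages in those libraries would raise their markers by at least 0.366, 0.5 of that shift, but the 18 markers had a median of −0.076 (0.5 times the interquartile range is 0.057). With any single library left out the median of the interferon list was at least 0.67. An effect of S3QEL that needs no IL-1α is not settled. In experiment 1 the median interaction was 0.23, positive for 22 of 26 genes, with camera p = 0.14 with an estimated correlation. The median and the number of positive genes met the bound written against this explanation, but a camera p under 0.05 was required as well. *Ifit1* was at 0.321 to 0.79 FPKM in vehicle and 5.1 to 7.59 with IL-1α. Near 0 the pseudocount of 1 makes changes of equal ratio smaller, so a positive interaction can arise there without a different effect. For such genes the test cannot decide. An action of the compound on interferon signalling stays open and was not tested.

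*Fbxw7*, a ubiquitin ligase subunit gene chosen after its values were seen, was listed at 13148 to 120920 FPKM in 7 libraries of experiment 2 and at 9.69 to 12.8 in the other 8. High values did not need a treatment, since vehicle had 1 high library and 4 of 5 groups held both high and low libraries. There were 2 high libraries each with S1QEL, IL-1α and IL-1α plus S1QEL, and 0 with IL-1α plus S3QEL. With 3 libraries per group, an effect of S3QEL on how often high values occur is not excluded. A very short transcript in the gene's model is a possible source, because FPKM divides by an effective length that approaches 0. Genes whose highest library is over 50 times their median had a transcript or locus under 200 nt in 154 of 155 cases, against 232 of 12675 others (odds ratio 8.24e+03, 95% interval from 1.38e+03). Many of these are small RNA genes that are short as a whole, such as U6 genes, so the odds ratio cannot settle the case of *Fbxw7*. The shortest *Fbxw7* transcript has 56 nt in the GRCm38 annotation, which is not the build in the submitters' notes. The high values take up to 20% of the FPKM sum of a library, and the U6 genes named in the report are also short, so their FPKM may be inflated in the same way.

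Interactions of 22 gene lists and 1 gene were flagged by a test of the difference itself, but each of the list calls, made by camera with its preset correlation (adjusted p from 9.08e-28 to 0.0376), was lost with an estimated correlation (lowest adjusted p = 0.0685), so a difference is not established for any list. For S3QEL with against without IL-1α in experiment 1, the median log2 interaction was −0.245 for chemokines, −0.132 for STAT3 targets, 0.234 for interferon-stimulated genes, −0.113 for pan-reactive genes, −0.122 for complex I subunits, −0.0947 for subunits of complexes II, IV and V, −0.0762 for glycolysis, −0.114 for the integrated stress response, −0.127 for hypoxia-inducible factor targets and −0.0843 for ribosomal proteins. For S1QEL in experiment 2 it was 0.135 for cytokines, −0.0681 for STAT3 targets, 0.342 for interferon-stimulated genes, 0.122 for the A1 list, 0.107 for MHC class I, 0.267 for mitochondrially encoded mRNAs, −0.081 for glycolysis, −0.122 for hypoxia-inducible factor targets, 0.0813 for matrix genes, −0.0615 for ribosomal proteins, 0.12 for neuron markers and −0.324 for ependymal markers. The U6 gene ENSMUSG00000119738 had an interaction with adjusted p = 1.73e-05.

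*Mllt10* and *Guk1* had opposite calls with IL-1α in the 2 experiments and were chosen after their values were seen. *Mllt10*, which encodes a cofactor of histone methylation, had 12.7 ± 0.896 FPKM against 10.6 ± 0.755 in vehicle in experiment 1 (n = 3 per group; log2 fold change 0.241, limma adjusted p = 0.0122) and 15.5 ± 1.28 against 18.8 ± 1.5 in experiment 2 (−0.268, adjusted p = 0.00583). The guanylate kinase gene *Guk1* had log2 fold changes of 0.149 (adjusted p = 0.0377) and −0.176 (adjusted p = 0.00668). The difference between experiments was not tested.

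For a contrast of 3 libraries with 3 there are 10 splits, which cannot give a share under 0.05. The real split gave the most genes in each of the 8 contrasts, so that 1 of 10 splits was as large. In experiment 1 these were 4669 genes with IL-1α, 37 with S3QEL and 30 with S3QEL during IL-1α, each against 1 gene in the highest other split. In experiment 2 they were 5081 with IL-1α (highest other 1), 16 with S1QEL (1), 56 with S1QEL during IL-1α (0), 2768 with S3QEL during IL-1α (3) and 1100 for S3QEL against S1QEL (0). In the other splits any treatment effect enters the spread within groups and lowers the count. Their counts are therefore not the level that chance alone would give. Chance is not excluded for the 1 interaction of S1QEL in experiment 2, since 22 of 100 splits drawn gave at least 1 gene. For S3QEL in experiment 1 the real count is 0, which all 100 splits reach by necessity, so that comparison says nothing. The highest other splits, with 340 and 195 genes, swap the compound arms with IL-1α or without it, and so add the compound's effects with and without IL-1α. Apart from these the highest were 4 and 5.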

How the results depend on the processing

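The alternatives with failed values as missing and with protein-coding genes alone were chosen after the data were seen. Where a result moved and no reason is given, the cause was not tested. Depth is unknown and limits all of these.

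The IL-1α counts (4669 and 5081) and the count for S3QEL during IL-1α in experiment 2 (2768) stayed within 1.5 times under every alternative but the fold of at least 1.5. Requiring that fold left 1122, 10 and 5 genes for IL-1α, S3QEL and S3QEL during IL-1α in experiment 1, and 1086, 5, 7, 215 and 63 for IL-1α, S1QEL, S1QEL during IL-1α, S3QEL during IL-1α and S3QEL against S1QEL in experiment 2.

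Small counts depended on the setting. S3QEL alone (37 genes) gave 3 without a filter, 68 with a filter at 5 FPKM, 2 with the replicate number as a block, 59 with protein-coding genes alone and 2 when only the groups in the contrast were fitted, which leaves fewer libraries for the variance. For S3QEL during IL-1α in experiment 1 (30) these last fits gave 1, and the block 19. S1QEL alone (16) gave 34 with the block and 2 on its own groups. S1QEL during IL-1α (56) gave 35 without a filter, 141 with the block and 12 on its own groups. S3QEL against S1QEL (1100) gave 690 without a filter and 457 on its own groups. The S1QEL interaction (1) gave 6 genes without a filter and 0 with protein-coding genes alone. The labels do not say whether a replicate number marks a shared culture, so the block has no basis in them. In no contrast did all 3 pairs correlate above 0.1. Some pairs did, such as 0.34 and 0.28 for IL-1α in experiment 2, where the other was −0.089. With 3 libraries per group this cannot exclude pairing.

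Leaving out each library in turn gave 3976 to 4148 and 4296 to 4686 genes for IL-1α and 2015 to 2268 for S3QEL during IL-1α in experiment 2. S3QEL alone ranged from 1 (without vehicle library 3) to 15 (without S3QEL library 1), and S3QEL during IL-1α in experiment 1 from 2 (without IL-1α library 1) to 22 (without IL-1α plus S3QEL library 1). S1QEL ranged from 6 (without S1QEL library 1) to 21 (without S1QEL library 3), and S1QEL during IL-1α from 15 (without IL-1α library 1) to 37 (without IL-1α plus S1QEL library 3). S3QEL against S1QEL ranged from 479 (without IL-1α plus S1QEL library 1) to 704 (without IL-1α plus S1QEL library 2). The interactions gave 0 to 1 (S3QEL) and 1 to 2 (S1QEL).

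With an estimated correlation the lists called fell from 18 to 7 and from 19 to 9 for IL-1α, and to 0 from 5, 10 and 10 for S3QEL, S3QEL during IL-1α and its interaction in experiment 1, and from 8, 17, 13, 14 and 12 for S1QEL, S1QEL during IL-1α, S3QEL during IL-1α, S3QEL against S1QEL and the S1QEL interaction. The last gave 6 without a filter. With single libraries left out the lists called ranged from 4 to 10 for S3QEL alone (10 without S3QEL library 3) and from 10 to 21 for S1QEL during IL-1α. Of 326 list results, a pseudocount of 0.1 kept 322, no filter 301, median-ratio scaling 320 and the block 319 on their side of the threshold, and none reversed.

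The IL-1α sets lost every call with an estimated correlation, at unchanged medians: lowered set −0.0925 (S3QEL, experiment 1), −0.102 (S1QEL), −0.15 (S3QEL, experiment 2), −0.0873 (S3QEL against S1QEL) and −0.0624 (S1QEL interaction); raised set −0.064 (S3QEL interaction), 0.0629 (S1QEL) and 0.0495 (S1QEL interaction). With sets of all genes called, the raised set reversed to 0.0107 from −0.0364 for S3QEL in experiment 1 and to 0.0353 from −0.0307 for S3QEL against S1QEL. It became called at 0.0284 (S3QEL alone), 0.0194 (S1QEL alone) and 0.0568 (S3QEL, experiment 2) and was no longer called at −0.0195 (S3QEL interaction), and the lowered set became called at −0.0202 (S3QEL alone). Without a filter the raised set was called at 0.0215 (S3QEL, experiment 2) and −0.045 (S3QEL against S1QEL). A pseudocount of 0.1 ended the call at −0.0547 (S3QEL interaction). Median-ratio scaling ended the call of the lowered set at −0.0635 (S3QEL, experiment 1) and called the raised set at 0.0388 (experiment 2). With single libraries left out, medians were −0.101 to −0.0298 (raised, S3QEL interaction), −0.0769 to −0.00204 and −0.132 to −0.0538 (raised and lowered, S3QEL, experiment 1), −0.124 to −0.0722 (lowered, S1QEL), 0.00114 to 0.0632 and −0.186 to −0.13 (raised and lowered, S3QEL, experiment 2) and −0.0608 to 0.0112 and −0.0937 to −0.0463 (raised and lowered, S3QEL against S1QEL). The raised set with S1QEL during IL-1α depended on single libraries, with a median of 0.022 without IL-1α plus S1QEL library 3 and 0.102 without library 2 of that group. Without IL-1α the medians were 0.00855 to 0.0241 and −0.086 to −0.0222 (raised and lowered, S3QEL) and 0.00476 to 0.0216 and −0.0228 to 0.00992 (raised and lowered, S1QEL), and the lowered set of the S3QEL interaction had −0.0697 to −0.0126. The S1QEL interaction of the raised set was 0.00927 without IL-1α plus S1QEL library 3 and at most 0.0771, and that of the lowered set was −0.0905 to −0.056.

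Without a filter the correlations between experiments fell from 0.884 to 0.824 (r) and from 0.827 to 0.628 (rho) for IL-1α and from 0.386 to 0.283 and 0.469 to 0.301 for S3QEL during IL-1α, with 15 shared calls in place of 26 and 28 in place of 51 shared by S1QEL and S3QEL. A pseudocount of 0.1 gave r = 0.844 for IL-1α and raised the covariance of S1QEL and S3QEL effects from 0.0338 to 0.0667. With single libraries left out, r was 0.858 to 0.881 and rho 0.794 to 0.827 for IL-1α, and r 0.327 to 0.387 for S3QEL. Shared S3QEL calls were 2 (without IL-1α library 1 of experiment 1) to 26, and calls shared by S1QEL and S3QEL 13 (without IL-1α library 1 of experiment 2) to 53.

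Of the named genes called, 85 of 87 (IL-1α), 1 of 22 (S3QEL) and 1 of 20 (S3QEL during IL-1α) kept the call under every alternative in experiment 1, and 88 of 91 (IL-1α), 1 of 13 (S1QEL), 3 of 27 (S1QEL during IL-1α), 58 of 66 (S3QEL during IL-1α) and 29 of 55 (S3QEL against S1QEL) in experiment 2. *Fabp7* reversed with quantile normalization, from −0.26 to 0.0253 for S3QEL against S1QEL.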

Other observations

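Each of the tests in this part was chosen after the result was seen, and so were the 3 gene lists and the genes named from them. The camera p-values come from a model across genes with 3 libraries per group and are not exact tests.

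Lysosome and V-ATPase genes had small positive medians as a list with both compounds, with and without IL-1α, though few passed singly outside S3QEL during IL-1α in experiment 2. *Atp6v1b2*, which encodes a subunit of the pump that acidifies lysosomes, rose in all 5 contrasts of a compound with its control, by log2 fold changes of 0.23 (adjusted p = 0.0372) and 0.24 (0.0291) with S3QEL in experiment 1, 0.32 (0.00269) and 0.35 (0.00117) with S1QEL, and 0.78 (5.57e-08) with S3QEL during IL-1α in experiment 2. The sialidase gene *Neu1* rose by 0.37 with S1QEL and 0.76 with S3QEL during IL-1α in experiment 2. Over 46 genes the median was 0.08 and 0.06 with S3QEL alone and during IL-1α in experiment 1 (1 rise in each, 1 and 3 over the list alone), 0.06 and 0.06 with S1QEL alone and during IL-1α (1 and 3 rises, 4 and 8 over the list alone), and 0.12 with S3QEL during IL-1α in experiment 2, where 17 genes rose, 23 over the list alone. Camera with an estimated correlation gave adjusted p = 0.0188, 0.0365, 0.00208, 0.00264 and 0.00383. S3QEL against S1QEL gave 8 genes higher (median 0.05, adjusted p = 0.0204). IL-1α itself gave 10 and 14 falls and 1 rise in each experiment (adjusted p = 0.163 and 0.114).

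The unadjusted p of camera with an estimated correlation was 0.00628 for S3QEL alone and 0.000693 for S1QEL alone, but these values are part of the pattern itself and do not test it, so an effect common to both compounds or to both experiments stays open. S1QEL alone was set against vehicle, so the IL-1α libraries that both contrasts share in experiment 2 have no part in its shift. In experiment 1 microglia and macrophage markers moved with the list and by more (median 0.16 with S3QEL alone, 17 of 18 above 0, adjusted p = 0.112; 0.08 during IL-1α, 16 of 18, adjusted p = 0.224), so a higher share of these cells stays open there. In experiment 2 their medians were −0.04 and −0.11 with S1QEL alone and during IL-1α and −0.08 with S3QEL, opposite to the list. Ribosomal protein genes were also above 0 in 41 of 48 with S3QEL alone (median 0.06) and 43 of 48 with S1QEL alone (0.05), so without IL-1α a small upward shift was not particular to lysosome genes. During IL-1α ribosomal protein genes were above 0 in 12 of 48 with S3QEL in experiment 1 (median −0.02) and 17 of 48 with S1QEL (−0.02). With S3QEL in experiment 2 the share was 31 of 48 (0.02).

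p53 target genes rose with IL-1α, among them *Eda2r* (1.16 in experiment 1 and 1.14 in experiment 2), *Btg2* (0.90 and 0.89) and *Cdkn1a* (0.78 in both). Of 23 genes, 16 rose and 1 fell in experiment 1 (median 0.46, adjusted p = 0.0288 with an estimated correlation), and 16 rose and 2 fell in experiment 2 (0.40, 0.00318). S3QEL during IL-1α in experiment 2 raised 14 and lowered 1 (0.22, 0.00411), and S3QEL was above S1QEL for 12 (0.22, 0.00219). An effect of S3QEL present in both experiments is not settled: in experiment 1 during IL-1α the median was 0.08 with 0 genes called and camera p = 0.0656 with an estimated correlation. The bound that would have counted against this explanation was moved, after that p was seen, from a p of at least 0.05 to a median of 0 or below, and under the earlier bound the test would have counted against it. With S3QEL alone the adjusted p was 0.165, and with S1QEL 0.53 alone and 0.77 during IL-1α.

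Aminoacyl-tRNA synthetase genes, 18 of them measured, had a median of 0.09 with S3QEL alone and 0.09 during IL-1α in experiment 1 (adjusted p = 0.0341 and 0.0365 with an estimated correlation). The microglia and macrophage markers given above had positive medians in the same contrasts, as ribosomal protein genes had with S3QEL alone, so this shift was not particular to synthetase genes. *Eprs* (0.22, adjusted p = 0.0372) was the only gene called, with S3QEL alone. During IL-1α in experiment 2 S3QEL raised 4 (0.10, adjusted p = 0.179). S1QEL gave adjusted p = 0.4 alone and 0.595 during IL-1α, S3QEL against S1QEL 0.241, and IL-1α 0.163 (5 rose and 1 fell) and 0.114 (7 rose).

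A fall of *Txnip* could reflect a fall of all targets of the glucose sensor MondoA, of which *Arrdc4* is another. *Arrdc4* was not down by 0.5 of the fall of *Txnip* in 3 contrasts of experiment 2: S1QEL during IL-1α (−1.67 for *Txnip* and −0.14 for *Arrdc4*, SE 0.0998 and adjusted p = 0.685 for *Arrdc4*), S3QEL during IL-1α (−2.34 and −0.13, SE 0.0998, 0.409) and S3QEL against S1QEL (−0.67 and 0.02, SE 0.0998, 0.952). All 3 were during IL-1α and share libraries, so they are not separate tests. The bound of 0.5 and *Arrdc4* as the only other target were choices, so the test cannot exclude a fall of MondoA targets. The test also counted S3QEL alone (−1.21 and −0.29, SE 0.0661, 0.103) and during IL-1α in experiment 1 (−1.24 and −0.37, SE 0.0661, 0.0506), 5 contrasts in all, but there *Arrdc4* was more than 2 SE below 0 without being called, so these are not held against a joint fall. With S1QEL alone both genes fell (−1.65 and −0.73, 0.00953).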
